A study of Homo sapiens with 4 samples.

How the data were processed

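RNA was measured in 4 established human colon cell lines grown as spheroids, with 1 library per line: HCEC-1CT, HCT116, DLD-1 and SW620. Per the labels' protocols, cells were seeded in low-attachment plates of 24 wells in medium with 10% fetal bovine serum and grown for 7 days. Compact spheroids were picked under a microscope, total RNA was pooled from 2 plates, and libraries were built by a standard Illumina protocol. Whether poly(A) selection or ribosomal depletion was used, and whether libraries kept strand, is not given in the sources used here.

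The values used are FPKM, in which fragments are scaled to transcript length and library size, as deposited by the authors, in a table of genes and a table of transcripts. Per the submitters' processing notes, FastQC and HISAT2 were used with the genome build hg38, without versions. The program that made the FPKM values, its annotation release and any filter are not given in the sources used here. The tables hold 58740 genes and 207345 transcripts. Of the gene IDs, 58275 were matched to GENCODE 29 (GRCh38), and 96.7% of them had the same coordinates there, so gene types and transcript lengths were taken from that release. Another 345 entries are loci that the tables name without a known gene. Each gene value equalled the sum of its transcripts to within 0.00220 FPKM. In each of the 2 tables, 1 column of values matches no sample and was not used.

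No counts are given, so the depth was read from low values. In genes with a single transcript, FPKM multiplied by transcript length peaked at whole multiples of a step that differed between libraries. Of 3601 to 4210 values tested per library, 347 to 460 lay within a tolerance of 0.01 of 1 step, against 6 to 14 at 1.25 steps. The step was taken as the most frequent low value, so that peak was given by construction. At 2 steps there were 203 to 213 values, against 6 to 12 lying 0.25 steps further on. At 3 steps there were 89 to 112, against 5 to 9. Many values lay elsewhere. The steps correspond to about 29500000 fragments in HCEC-1CT, 25300000 in HCT116, 23300000 in DLD-1 and 28700000 in SW620. At these depths 1 FPKM of a transcript of 2 kb stands for 59.0, 50.6, 46.7 and 57.5 fragments. Counting error is therefore small beside a 4-fold difference at 1 FPKM, and the lack of a second library per line limits the comparisons.

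Because each line has 1 library, no test and no p-value was computed, and the 3 cancer lines were not treated as replicates of each other. Ratios are log2 ratios of FPKM plus a pseudocount of 1, which understates the change of low genes. A gene was counted as higher or lower at 4-fold or more with at least 1 FPKM in the higher library, a limit that 4-fold with this pseudocount already meets. It was counted in all 3 cancer lines when it passed in the same direction in each, and it set a line apart when it lay 4-fold above, or 4-fold below, each of the other 3 lines. Since all 3 ratios share the HCEC-1CT library, the overlap was set beside that of independent lists and beside simulated unchanged lines.

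Before the data were examined, 43 gene lists of 1062 entries were fixed from textbook knowledge; 6 entries matched no gene of the table. For each list the median log2 ratio was taken over members with at least 1 FPKM in 1 or more libraries. Its percentile was read among 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins. A list was called when the percentile lay under 2.5, or over 97.5, in all 3 cancer lines; members within lists were counted at 2-fold. The filter lets in genes that are high in any line, so a list with few measured members leans towards the line that lets them in. The percentiles describe these libraries and are not tests.

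Named genes followed a rule fixed beforehand. For all 3 cancer lines these were the 12 genes per direction with the largest smallest-of-3 log2 ratio and at least 10 FPKM in the higher libraries. For each single line they were the 5 per direction with the largest log2 ratio, and for each line set apart the 6 per direction with the widest gap. Within a list they were 2 to 6 members with the largest median ratio, members that passed in the other direction, and any driver or immortalisation gene. A transcript switch was counted for genes with at least 2 transcripts and a summed FPKM of at least 5 in both libraries. The most abundant transcript had to differ, and the HCEC-1CT main transcript had to lose at least 50 percentage points of the gene's total; the 6 largest losses and a set of genes fixed beforehand were looked up. Some planned results are not reported here.

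Where a gene is listed at 0 in a library, its values are given and no fold. None of the 58 housekeeping and ribosomal protein genes in the lists was listed at 0 in any library, while 30 genes with at least 10 FPKM in every cancer line were listed at 0 in HCEC-1CT. Genes with near-identical copies, such as the histone, HLA and MAGEA genes, and genes that overlap others are less certain, since how shared reads were assigned is not given in the sources used here.

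Alternatives were other pseudocounts, filters, folds and scalings, the summed transcript table, protein-coding genes alone, entries with the same symbol summed, each cancer line left out of the shared count, unmatched random lists and other limits for transcripts. The scaling to the nuclear protein-coding total and random lists of nuclear protein-coding genes were added after the data were seen. The counting rule was checked on simulated data for the genes higher or lower in all 3 cancer lines. The changed genes were drawn from those with at least 5 FPKM in HCEC-1CT, so the shares called do not apply to genes near 0 there. With an assumed log2 SD of 0.25 it called 80% of 50 genes changed 8-fold, 6% of 50 changed 4-fold and 0 of 13622 unchanged genes. With an SD of 0.5 it called 66%, 18% and 0 of 14190. No larger SD was run in this check, so the 0 false calls hold for these settings only. In the simulated unchanged lines an SD of 1 gave a mean of 50.9 higher and 87.0 lower genes. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with GENCODE 29 as the only reference.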

Results

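Gene expression was profiled by RNA sequencing in spheroids of 4 human colon cell lines, with 1 library per line and therefore no replicates. HCEC-1CT is a line from non-cancerous colon that was made immortal with CDK4 and TERT, and the labels give it as epithelial. HCT116 and DLD-1 come from colorectal carcinomas, and SW620 comes from a lymph node metastasis of one. The libraries corresponded to about 29500000, 25300000, 23300000 and 28700000 fragments in HCEC-1CT, HCT116, DLD-1 and SW620, and every series of 4 values is given in that order. At least 1 FPKM was reached by 13289, 14418, 14654 and 14084 genes. Nuclear protein-coding genes held 68.0%, 53.5%, 67.4% and 61.9% of the summed FPKM, genes of the mitochondrial genome 1.79%, 10.6%, 3.42% and 3.91%, and the abundant small RNAs 7SL and 7SK 15.9%, 19.8%, 11.7% and 16.5%. By the median ratio over genes at 1 FPKM or more in all libraries, the cancer lines lay 0.38, 0.41 and 0.29 above HCEC-1CT on the log2 scale, in the order HCT116, DLD-1 and SW620. All ratios are of FPKM as deposited and include that shift.

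The main question was how the 3 cancer lines differ from the non-cancerous line. All 3 cancer lines carried high levels of epithelial genes that were at or near 0 in HCEC-1CT. The HCEC-1CT library instead held mesenchymal, matrix, protease and cytokine transcripts that were mostly far lower in the cancer lines. The lists of cell cycle genes, Wnt targets and cholesterol synthesis genes lay above random lists in all 3 cancer lines, though most Wnt and cholesterol genes were not 2-fold higher in every line. By the 4-fold rule 500 genes were higher and 558 lower in all 3 cancer lines, of 18637 genes with at least 1 FPKM in 1 or more libraries; 478 and 470 of them were protein coding. The balance depends on the settings: it was 420 and 686 with median-ratio scaling and 86 and 259 with a pseudocount of 5, but 1103 and 979 with a pseudocount of 0.1 and 1743 and 1325 at 2-fold.

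Several of the largest shared increases were in epithelial genes. KRT19, a keratin of simple epithelia on chromosome 17, 41523617 to 41528308 in hg38 (ENSG00000171345), was listed at 0, 567, 1555 and 1664 FPKM. KRT8 and its partner KRT18 stood at 3.10, 600.5, 1856 and 3122 FPKM and at 4.05, 194, 1043 and 1543 FPKM. EPCAM, an adhesion molecule of epithelia (chromosome 2, 47345158 to 47387601, ENSG00000119888), was listed at 0, 144, 406 and 237 FPKM, and the protease inhibitor SPINT2 at 0, 126, 174 and 210.1 FPKM. The desmosome gene DSP was listed at 0, 48.4, 88.0 and 97.9 FPKM and E-cadherin, CDH1, at 0, 27.2, 189 and 129 FPKM. Of the 34 measured genes for epithelial junctions and differentiation, 27 were 2-fold or more higher in all 3 cancer lines and 0 were lower, and 30 had under 1 FPKM in HCEC-1CT. The list medians were 4.49, 5.55 and 3.41 on the log2 scale in HCT116, DLD-1 and SW620, and those of the 5 simple keratins 5.27, 7.69 and 8.26, all above the random lists. SFN, a 14-3-3 protein of epithelia, had log2 ratios of 7.20, 8.21 and 6.49. The matriptase gene ST14 had 6.47, 7.02 and 6.22, S100A14 5.55, 7.64 and 6.27, and TINAGL1 5.42, 5.97 and 7.04. C19orf33 was listed at 0, 66.5, 104 and 79.8 FPKM.

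Several of the largest shared decreases were in genes for proteases, their inhibitors and other secreted proteins. TFPI2, an inhibitor of serine proteases (chromosome 7, 93885397 to 93890991, ENSG00000105825), was listed at 2053, 0.0322, 0 and 0 FPKM. The metalloproteinase genes MMP3, MMP1 and MMP2 stood at 1299.6, 829 and 619 FPKM in HCEC-1CT, and none of them reached 1 FPKM in a cancer line. STC1, a secreted hormone, stood at 1360.4, 0.0807, 0.539 and 0.0357 FPKM and IGFBP5, which binds insulin-like growth factors, was listed at 351, 0.0985, 0 and 0.0112 FPKM. Of the 19 measured matrix proteases and inhibitors, 12 were 2-fold or more lower in all 3 cancer lines and 3 were higher (SERPINB5, MMP15 and TIMP3). The list median was -3.88 in each of the 3 lines. With 19 members the median is the ratio of 1 gene, and the identical values point to a member at the same level in each line. They are therefore not 3 separate agreements.

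Cytokine genes were among the largest decreases. CXCL8, the neutrophil chemokine interleukin 8 (chromosome 4, 73740506 to 73743716, ENSG00000169429), stood at 10944, 3.71, 2.32 and 13.3 FPKM and made up 3.90% of the nuclear protein-coding FPKM of HCEC-1CT. PTGS2, the inducible cyclooxygenase, was listed at 4262, 1.80, 5.41 and 0 FPKM, IL1B at 1193, 0, 0.283 and 0.231 FPKM and IL6 at 1118, 0, 0 and 0 FPKM. CSF3, the granulocyte growth factor, was listed at 740.3, 0, 0 and 0.182 FPKM and IL24 at 561, 0, 0 and 0 FPKM. Of the 28 measured NF-kB targets, cytokines and chemokines, 23 were lower in all 3 cancer lines by 2-fold or more and 1 was higher. The medians were -6.70, -5.50 and -5.43. The list of CDK inhibitors and senescence genes, which shares several cytokines with it, had medians of -0.91, -1.63 and -1.12; 8 of 19 members were lower in all 3 lines, namely 7 cytokines and IGFBP3, and LMNB1 and CDKN1C were higher. LMNB1, the nuclear lamina protein lamin B1, stood at 1.04, 12.3, 25.5 and 6.25 FPKM.

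Mesenchymal and matrix genes were low in the cancer lines. Of 35 measured mesenchymal transition genes, 23 were 2-fold or more lower in all 3 lines, with medians of -3.51, -4.61 and -2.91. The ligand WNT5A was listed at 497, 0.0256, 1.27 and 0 FPKM, the matrix protein TNC at 249, 0.0196, 0.0476 and 62.4 FPKM and the BMP antagonist GREM1 at 146, 0, 0 and 0 FPKM. VIM, the intermediate filament vimentin, was lower by less in SW620, at 572, 1.16, 0.858 and 223 FPKM. S100A4 went the other way, at 3.99, 183, 98.7 and 2051 FPKM. Of 33 measured collagen and matrix genes, 24 were lower in all 3 lines and 5 higher; COL1A2 was listed at 208, 0, 0 and 0 FPKM and COL3A1 at 198, 0.256, 0 and 0.00620 FPKM. The markers of fibroblasts and pericytes, fixed as markers of cells other than the cultured lines, moved with these groups. That list shares COL1A1, COL1A2, COL3A1, DCN and LUM with the collagen and matrix list, so part of this agreement is the same genes. Of 13 measured fibroblast and pericyte markers, 11 were lower in all 3 cancer lines, and all 13 had at least 1 FPKM in HCEC-1CT. Their summed FPKM was 1181, 54.5, 2.09 and 34.2, against 31.2, 1307, 2956 and 1571 for the epithelial junction list. PDGFRA, a growth factor receptor of fibroblasts, was listed at 109.7, 0.0180, 0 and 0.0102 FPKM, the matrix proteoglycan DCN at 191, 0.0303, 0 and 0.0144 FPKM and the glycoprotein PDPN at 67.8, 0.0255, 0 and 0 FPKM. The medians were -5.92, -6.10 and -4.71.

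Proliferation genes were higher in the cancer lines. Of 43 cell cycle genes, 30 were 2-fold or more higher in all 3 lines and 1, the D-type cyclin CCND2, was lower; 27 had under 1 FPKM in HCEC-1CT. The medians were 2.38, 3.48 and 1.95. TOP2A, a topoisomerase of dividing cells, stood at 0.909, 13.2, 48.4 and 26.2 FPKM, the mitotic kinase CDK1 at 0.355, 18.4, 41.3 and 25.6 FPKM and the thymidine kinase TK1 at 0.549, 42.2, 35.1 and 15.9 FPKM. Histone genes without poly(A) tails, fixed as a sign of library preparation, had medians of 1.13, 3.56 and 2.09, with 17 of 36 higher in all 3 lines; in HCT116 18 were higher and 6 lower. Wnt and beta-catenin targets had medians of 0.88, 1.59 and 2.79, with 11 of 29 higher in all 3 and 0 lower. The crypt transcription factor SOX9 was listed at 0, 85.9, 91.1 and 137 FPKM, AXIN2, a feedback inhibitor of the pathway, stood at 0.767, 8.16, 234 and 55.4 FPKM, RNF43 at 0, 15.8, 56.9 and 27.0 FPKM and MYC at 8.26, 80.8, 17.5 and 57.8 FPKM. In HCT116 the Wnt list was just past the limit, at the 97.7 percentile, and with a pseudocount of 5, scaling to the protein-coding total or random lists of protein-coding genes it fell short there.

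Smaller shifts were seen in metabolic and signalling groups. Cholesterol synthesis genes had medians of 1.16, 2.21 and 1.38, with 9 of 20 higher in all 3 lines; MSMO1 stood at 12.2, 48.1, 297 and 105 FPKM and FDFT1, squalene synthase, at 12.6, 47.8, 119.7 and 92.5 FPKM. The amino acid and ER stress list was below the random lists, with medians of -0.27, -0.91 and -0.31, but only 3 of 23 members were 2-fold lower in all 3 lines and 1 was higher, and in HCT116 6 were higher and 6 lower. In it the ER chaperone HSPA5 stood at 646, 367, 117 and 210.3 FPKM and DNAJB9 at 84.4, 14.8, 9.48 and 12.9 FPKM, while the serine synthesis enzyme PSAT1 stood higher, at 4.16, 28.3, 35.3 and 27.2 FPKM. The TGF-beta and BMP list had medians of -0.39, -0.35 and -0.55, with 7 of 31 lower and 2 higher in all 3 lines. BMP2 was listed at 324, 0, 8.73 and 0.0676 FPKM and INHBA, the activin A subunit, at 143, 0.00652, 0 and 0 FPKM. BMP4 and ID1 went up, with BMP4 at 0.261, 52.7, 131 and 64.1 FPKM and ID1, a BMP target, at 19.2, 209, 415 and 190.1 FPKM. The 13 mitochondrial messenger RNAs, fixed as a sign of library quality, had medians of 3.51, 1.03 and 1.66, with 6 higher in all 3 lines. MT-ND4 split, at 451, 8027, 99.5 and 2544 FPKM. This call was lost in DLD-1 among members at 5 FPKM or more and with unmatched random lists.

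**Figure D1:**
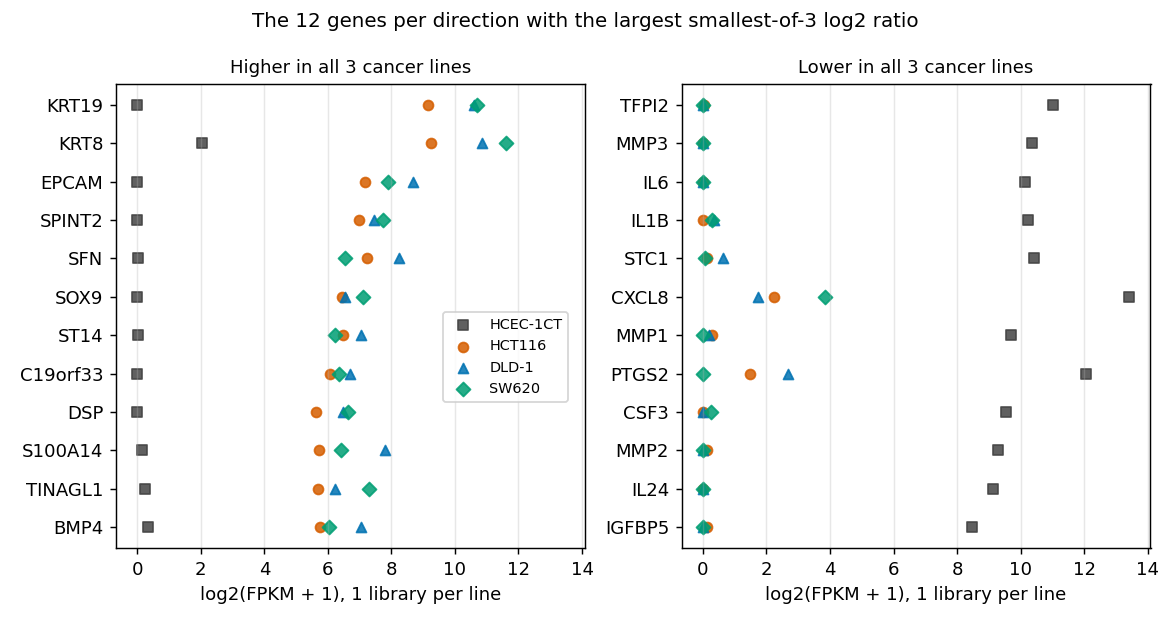
Each point is the log2(FPKM + 1) of a gene in 1 library, for the 12 genes per direction chosen by the fixed rule. The 12 higher genes sit near 0 in HCEC-1CT except KRT8, at 3.10 FPKM, and among the 12 lower genes only CXCL8 and PTGS2 exceed 1 FPKM in a cancer line.

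These counts describe 4 libraries and cannot separate cancer from other differences between HCEC-1CT and the rest. Among the 14495 genes past the filter in all 3 comparisons, 1223, 1292 and 1195 were higher and 933, 1039 and 1023 lower in HCT116, DLD-1 and SW620; independent lists of those sizes would share 8.99 and 4.72 genes. Simulated unchanged lines gave a mean of 0.05 and 0.15 with a log2 SD of 0.5 but 50.9 and 87.0 with an SD of 1, so part of the overlap may come from the shared HCEC-1CT library. In these simulations a gene listed at 0 in HCEC-1CT stays at 0. They therefore cannot show how many increases from 0, such as KRT19 and EPCAM, come from that library.

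**Figure D2:**
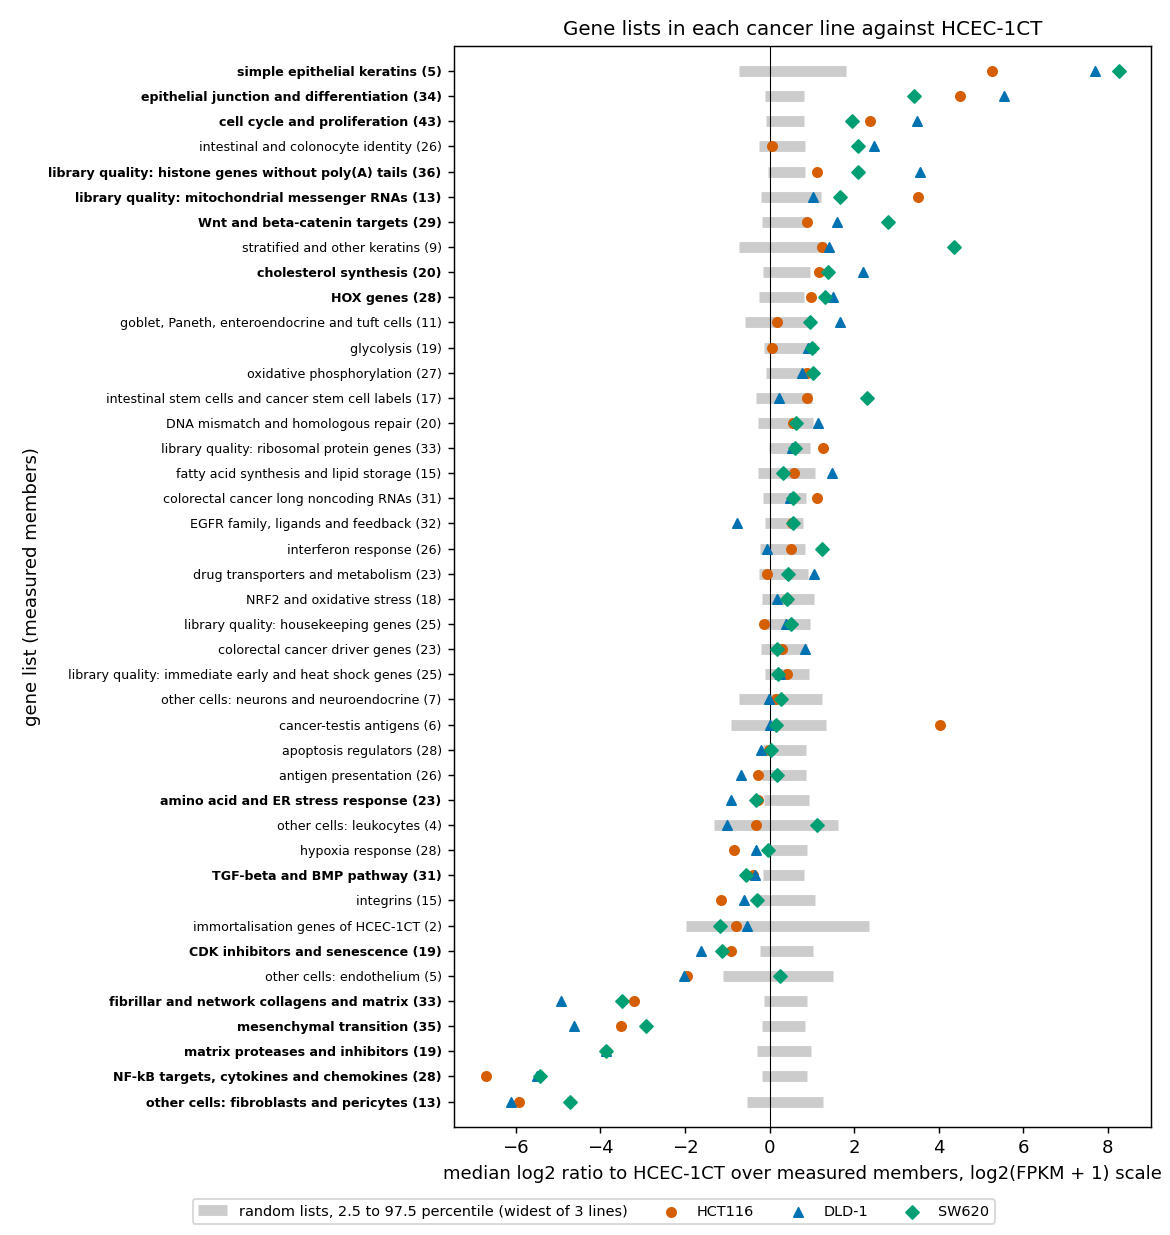
Points are the median log2 ratio to HCEC-1CT of the gene lists shown in HCT116, DLD-1 and SW620, and grey bars are the range of random lists matched on expression. The 8 lists called above and the 8 called below the random lists in all 3 lines are in bold type, from simple epithelial keratins at the top to fibroblast markers at the bottom.

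Each cancer line was also set against HCEC-1CT alone. In HCT116, 1684 genes were higher and 933 lower. The 5 largest increases were KRT19, SFN, KRT8, EPCAM and SPINT2, and the 5 largest decreases CXCL5, CXCL8, TFPI2, PTGS2 and CXCL1. CXCL5 was listed at 3320.3, 0, 76.2 and 0.348 FPKM and CXCL1 stood at 2899, 1.20, 0.943 and 9.96 FPKM. Of 31 cancer-testis antigens only 6 reached 1 FPKM in any library, with 4 higher in HCT116 by 2-fold or more and 2 lower; PRAME was listed at 0, 17.1, 0 and 0.621 FPKM. Ribosomal protein genes had a median of 1.27, above the random lists, and housekeeping genes -0.13, below; both lists were fixed as signs of library quality and lay within the range in DLD-1 and SW620. Long noncoding RNAs had 1.11, above. The hypoxia list was below in HCT116 and DLD-1, with medians of -0.84 and -0.32, and just within the range in SW620, at the 2.52 percentile; LOX, which cross-links collagen, stood at 149, 0, 0.0904 and 0.267 FPKM. Integrins were likewise below in both, with -1.14 and -0.61, and just within the range in SW620, with ITGA1 at 47.1, 0.0969, 0.431 and 1.31 FPKM. With median-ratio scaling the split for HCT116 was 1355 higher and 1187 lower, and on the TPM scale, with equal library totals, 1873 and 1679.

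In DLD-1, 1722 genes were higher and 1039 lower. The largest changes were again in KRT19, KRT8, EPCAM and SFN, joined by CD24, a surface glycoprotein, at 0, 22.0, 259 and 143 FPKM. The decreases were led by CXCL8, TFPI2, CXCL1, MMP3 and PLAT, the tissue plasminogen activator, which stood at 1347 FPKM in HCEC-1CT and below 1 FPKM in DLD-1. The intestinal and colonocyte list had a median of 2.48, above the random lists, with 20 of 26 higher by 2-fold or more and 1 lower. The cadherin CDH17 stood at 0.0551, 0.0833, 179 and 20.5 FPKM and the intestinal transcription factor HNF4A was listed at 0, 2.63, 17.5 and 24.4 FPKM. Of 25 goblet and other secretory cell genes 11 were measured, with 7 higher in DLD-1 and 1 lower, and 5 and 0 in SW620, with the trefoil peptide TFF3 at 0, 0, 65.8 and 186 FPKM and AGR2 at 0, 0, 191 and 9.42 FPKM. Fatty acid synthesis genes had 1.47, DNA repair genes 1.13 and drug transporters 1.06, all above. The desaturase SCD stood at 44.2, 113, 1029 and 267 FPKM. Antigen presentation genes had -0.68 in DLD-1 and -0.28 in HCT116, below in both, with B2M at 479, 146, 44.1 and 292 FPKM. With median-ratio scaling the DLD-1 split was 1407 higher and 1284 lower.

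In SW620, 1665 genes were higher and 1023 lower. Of the 5 largest increases 3 were keratin genes (KRT19, KRT8 and KRT18), and the others were S100A4, a calcium-binding protein, and ITGB4, an integrin of hemidesmosomes, at 0.179, 47.0, 92.1 and 362 FPKM. The largest decreases were in PTGS2, CXCL5, TFPI2, STC1 and MMP3. The intestinal list had a median of 2.10 and stem cell genes 2.31, both above the random lists, with 17 of 26 higher by 2-fold or more and 2 lower in the first and 10 of 17 higher and 5 lower in the second. The mucin MUC13 was listed at 0, 0.400, 24.6 and 127 FPKM and the crypt factor ASCL2 at 0, 0, 117 and 43.7 FPKM. Stratified keratins had a median of 4.35, with 8 of 9 members higher by 2-fold or more and 0 lower, and were also above in DLD-1, at 1.40. Interferon response genes lay at the 99.99 percentile of random lists, with 14 of 26 higher by 2-fold or more and 4 lower, and with ISG15 at 14.8, 72.3, 38.7 and 131 FPKM and IFI6 at 8.39, 47.4, 7.04 and 81.3 FPKM. Whether such lists differ between the cancer lines was not tested.

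The 4 libraries were then compared for overall likeness and for the genes that set each apart, which is the only measure of spread between lines that the design holds. Pearson's r of log2(FPKM + 1) across 18637 genes, which are not independent replicates, was 0.69, 0.66 and 0.68 between HCEC-1CT and HCT116, DLD-1 and SW620. Among the cancer lines it was 0.79 for HCT116 and DLD-1, 0.83 for HCT116 and SW620, and 0.80 for DLD-1 and SW620. HCEC-1CT was set apart from the other 3 by 1058 genes, HCT116 by 272, DLD-1 by 394 and SW620 by 363. With 4 lines, any given one has a chance of 0.25 of having the highest count.

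**Figure D3:**
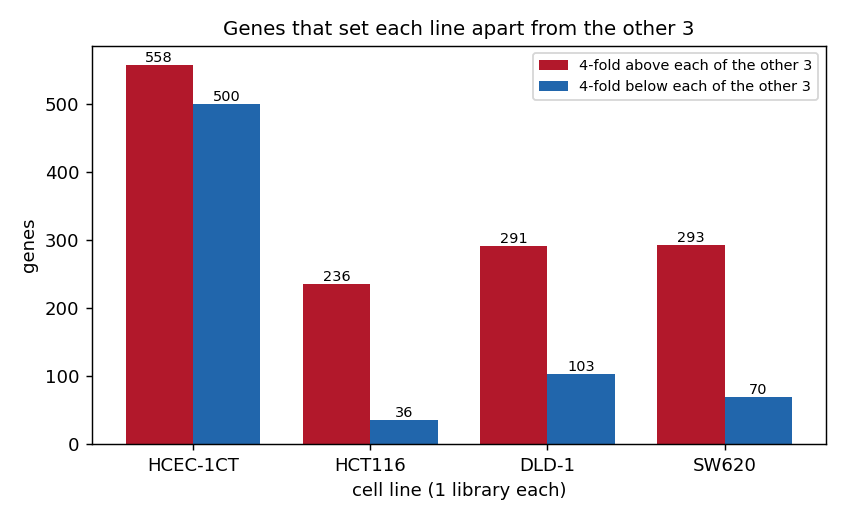
Bars count the genes that lay 4-fold above (red) or 4-fold below (blue) each of the other 3 lines, for each line. HCEC-1CT has 558 and 500 such genes, HCT116 236 and 36, DLD-1 291 and 103, and SW620 293 and 70.

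The genes furthest above the other lines in HCT116 included GTSF1 and MAGEB2, and several genes that all others expressed were at or near 0 there. GTSF1, a germ cell gene, was listed at 0, 77.7, 0 and 0.0603 FPKM and the cancer-testis antigen MAGEB2 at 0, 66.8, 0 and 0.627 FPKM. KRTAP2-3, CST6 and the pseudogene RPL32P29 were also among its leading genes. TXNIP, which binds thioredoxin and limits glucose uptake, was listed at 95.1, 0, 476 and 904 FPKM. TM4SF1 stood at 155, 0.188, 69.0 and 179 FPKM, the hyaluronan-binding CEMIP at 558, 1.05, 79.9 and 116 FPKM and the matrix protein TGFBI at 498, 0.564, 33.7 and 81.5 FPKM. The histone genes HIST1H1D and HIST1H1B were listed at 0 in HCT116.

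The genes furthest above the other lines in DLD-1 were of several kinds. PRR15L was listed at 0, 0.141, 156 and 0.304 FPKM, PHGR1 at 0, 0, 178 and 1.80 FPKM, the imprinted RNA H19 at 0, 0.869, 70.4 and 0.470 FPKM and the transcription factor FOXA1 at 0.107, 0.805, 63.1 and 0 FPKM. ERN2, an ER stress sensor of mucous epithelia, and the choline transporter SLC44A4 followed. The cytoskeletal linker MSN stood at 138, 47.0, 0.0217 and 181 FPKM, COL6A1 at 539, 68.8, 0.149 and 50.1 FPKM and DBN1 at 43.6, 53.3, 0.357 and 58.0 FPKM. ELOVL5, a fatty acid elongase, was listed at 25.8, 70.5, 0 and 58.8 FPKM, and AKR1B1 and TPM2 were likewise lowest in DLD-1.

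SW620 was set apart by FGF3, a growth factor listed at 0, 0, 0 and 103 FPKM, and by GPX2, a glutathione peroxidase of the gut, listed at 0, 0.438, 1.81 and 189 FPKM. ASPRV1, CLRN3, TOX3 and GJB1 followed. SMAD4, the shared mediator of TGF-beta and BMP signals (chromosome 18, 51028394 to 51085045, ENSG00000141646), stood at 30.8, 30.9, 43.8 and 0.156 FPKM. NT5E stood at 144, 30.5, 58.4 and 0.225 FPKM, TRIP6 at 22.8, 17.6, 20.6 and 0.254 FPKM and the metallothionein MT1E at 46.0, 23.1, 24.7 and 0.703 FPKM. TMED3 and the readthrough gene RPL17-C18orf32 were listed at 0. The growth factor receptor EGFR stood at 55.2, 38.9, 17.1 and 0.650 FPKM.

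Between the cancer lines, 921 genes were higher and 843 lower in HCT116 than in DLD-1. Against SW620, 632 were higher and 700 lower in HCT116, and 792 higher and 879 lower in DLD-1. Which line had more higher genes changed with the settings: on the TPM scale the split was 1075 and 1808 for HCT116 against DLD-1 and 1541 and 1148 for DLD-1 against SW620. Of colorectal cancer driver genes, APC stood at 5.74, 9.61, 8.64 and 6.58 FPKM, PIK3CA at 11.5, 4.77, 8.46 and 5.52 FPKM and CTNNB1, beta-catenin, at 61.3, 50.8, 111 and 141 FPKM. The genes used to make HCEC-1CT immortal stood at 2.83, 0.611, 1.09 and 0.171 FPKM for TERT and 33.1, 26.1, 29.2 and 21.3 FPKM for CDK4. The 3 lines differ in origin, and each value rests on 1 library.

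The transcript table was used to ask whether genes present in both lines changed their main transcript. The main transcript differed from that of HCEC-1CT, which had lost at least 50 percentage points, in 360 of 6630 genes in HCT116, 344 of 6634 in DLD-1 and 345 of 6503 in SW620, and in 94 of 5879 genes in all 3. In 49 of the 94 the new main transcript was the same in all 3 lines. RSBN1 went from ENST00000261441, with 91.9% of its FPKM in HCEC-1CT, to ENST00000612242, with 82.3%, 96.2% and 98.9% in the cancer lines. VPS35, a subunit of the retromer, went from ENST00000568784, annotated as a target of nonsense-mediated decay, with 85.3%, to the coding ENST00000299138, with 93.1%, 66.5% and 88.6%. MAPKAPK3, a kinase downstream of p38, went from ENST00000621469 with 89.2% to ENST00000357955 with 90.5%, 78.6% and 89.6%. PCGF2, IFNGR1 and PRRG1, which complete the 6 largest losses, each took more than 1 new main transcript across the 3 lines. SMAD7, TGFBR2 and LMNA kept the same main transcript in all lines, and CDH1, FGFR2 and VIM were under 5 FPKM in a library. CD44, ENAH, CTNND1 and PKM could not pass, so the rule does not speak to them. Their HCEC-1CT main transcripts held only 32.5%, 48.3%, 25.8% and 46.3%, too little to lose 50 points. In HCT116, DLD-1 and SW620 that share was 30.8%, 14.4% and 33.3% for CD44 and 16.2%, 7.77% and 12.2% for ENAH. It was 0.0780%, 0.0312% and 0.318% for CTNND1, and 0%, 0% and 9.07e-08% for PKM. With another line as the base, the same rule gave 90 genes for HCT116, 85 for DLD-1 and 77 for SW620, so HCEC-1CT did not stand out from the spread between lines. Independent lists of the switches among those 5879 genes would share 0.775, and splits between near-identical transcripts are uncertain in short-read estimates.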

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

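The tests of explanations given here were chosen only after the results were seen. The EGFR family, ligands and feedback list had a median of -0.77 in DLD-1, below random lists, and 0.56 in SW620, within their range, a gap of 1.33 on the log2 scale that was not tested. Its member DUSP4, a phosphatase that acts back on the MAP kinase pathway, stood at 1.57, 90.6, 2.68 and 75.0 FPKM in HCEC-1CT, HCT116, DLD-1 and SW620. The leukocyte marker list, of 4 measured genes, had a median of 1.13 in SW620 and lay 2.13 lower in DLD-1, which was not tested, and both values lay within the range of random lists; in SW620 it held LYZ at 24.5 FPKM and CD68 at 16.6 FPKM. Against HCEC-1CT, 34 genes were 4-fold higher in at least 1 cancer line and 4-fold lower in another, also untested. Chosen after the values were seen, the first by the smaller of the changes were HIST1H1B, listed at 14.9, 0, 296 and 76.2 FPKM, AKAP12, a scaffold protein, at 14.8, 221, 0.498 and 129 FPKM, and TXNIP, at 95.1, 0, 476 and 904 FPKM. Among the 345 loci without a known gene, which entered no gene list, 5 had at least 1 FPKM in all 3 cancer lines and were listed at 0 in HCEC-1CT. The highest lay on chromosome 6 from 144922332 to 144929952 (hg38), at 207 FPKM in HCT116, 2.90 in DLD-1 and 88.8 in SW620.

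The HCEC-1CT library was low in epithelial and high in fibroblast transcripts. A minority of fibroblasts mixed into an epithelial culture would leave the epithelial genes near the level of the cancer lines. That holds only if the epithelial cells of HCEC-1CT express these genes as the cancer lines do, which was not tested. Over 31 epithelial genes at 1 FPKM or more in all 3 cancer lines, the median HCEC-1CT level was 0.0849% of the lowest cancer line. Of these, 0 reached 50% and 3 reached 10%. The 31 genes come from the lists that showed the pattern, so these values restate it and are not a separate test. Other cells in place of HCEC-1CT and a mesenchymal state of the HCEC-1CT line itself cannot be told apart here: the smaller of the ratios of TERT and CDK4 to the highest cancer line was 1.13 (CDK4), TERT alone had 2.59, and 5 of 34 intestinal identity genes reached 1 FPKM, among them, chosen after the values were seen, KLF5 at 21.4 FPKM, which other cell types also express. A swap of labels with a cancer line was not tested, and DNA profiles of the cells were not analysed here. Other cells, a mesenchymal state and such a swap therefore remain open. So does a mixture, if the epithelial cells themselves express little of these genes. The shared counts would describe another contrast if the cells were not HCEC-1CT.

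The same library was low in cell cycle genes and high in cytokine genes. Library scaling alone is argued against by the size of the shift. Median-ratio scaling moved the cancer lines by 0.29 to 0.41 on the log2 scale, against cell cycle medians of 1.95 to 3.48. After it 30 of 43 cell cycle genes were still 2-fold or more higher in all 3 cancer lines, as many as in the values as deposited. With either scaling 23 cytokine genes were lower. With so small a shift these unchanged counts were nearly certain beforehand. Fewer cells in the cell cycle in the HCEC-1CT spheroids is a candidate explanation: the histone list, which shares no gene with the cell cycle list, lay above random lists in all 3 lines, with a lowest percentile of 99.94. That list was fixed as a sign of library preparation, and how the RNA was selected is not given, so a difference in preparation could move it too; in HCT116 6 of its 36 genes were 2-fold lower, and HIST1H1D and HIST1H1B were listed at 0. The low-attachment culture itself was shared by all lines. The kind of cell, its own response to growth in suspension, and a growth arrest with cytokine release all remain open as reasons. Each of these would come with the same 1 library.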

How the results depend on the processing

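All 24 genes named as higher or lower in all 3 cancer lines kept their direction and 4-fold size with 2 other pseudocounts and 3 scalings. They were chosen for the largest ratios, with a smallest absolute log2 ratio of 5.41, so this was nearly certain beforehand. It says nothing about genes nearer the 4-fold limit. No median of a called list changed sign in any alternative run. Without the filter the median of the 3 line medians moved most for fibroblast markers, from -5.925 to -3.76, endothelial markers, from -1.94 to 0, the intestinal list, from 2.10 to 0.93, matrix proteases, from -3.88 to -2.90, HOX genes, from 1.31 to 0.35, and goblet and other secretory cell genes, from 0.95 to 0.02; for cancer-testis antigens it went from 0.14 to 0. Dropping the filter and summing transcripts left every gene count as it was by construction, since 4-fold already needs more than 1 FPKM and the sums equal the gene values to within 0.00220 FPKM; other random lists cannot move a median. The number of called lists was 16 and ranged from 15 to 18. Wnt targets lost their call in 3 alternatives, and HOX genes and mitochondrial messenger RNAs in 2 each. Oxidative phosphorylation gained a call above random lists in 4, stratified keratins above in 3, integrins below in 3 and hypoxia below in 2. All 3 correlations among cancer lines stayed above those with HCEC-1CT with protein-coding genes, a pseudocount of 0.1, or a filter of 5 FPKM. The scaling to the nuclear protein-coding total and the background of nuclear protein-coding genes were chosen after seeing the data. Leaving out HCT116, DLD-1 or SW620 gave 1457, 1479 and 1383 shared genes, against 1058, more by construction. Depth limits genes near 1 FPKM least in HCEC-1CT, at about 29500000 fragments, and most in DLD-1, at 23300000. No paired analysis was possible because each line has 1 library and no result comes from a test.

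The pseudocount and the fold moved every count by construction, since they set how large a difference of low values must be. A pseudocount of 0.1 gave 4965, 4983 and 4935 genes in HCT116, DLD-1 and SW620 against HCEC-1CT, where the main counts were 2617, 2761 and 2688. It gave 2082 genes for all 3, which is also the count that sets HCEC-1CT apart, and 740, 1012 and 796 that set HCT116, DLD-1 and SW620 apart. It gave 3985, 2939 and 3732 between HCT116 and DLD-1, HCT116 and SW620, and DLD-1 and SW620. In the same order, a pseudocount of 5 gave 816, 1042 and 982 against HCEC-1CT, 345 for all 3, 52, 113 and 109 set apart, and 497, 380 and 516 between cancer lines. A 2-fold rule gave 7454, 7240 and 7260, then 3068, then 1315, 1845 and 1287, then 6418, 4920 and 6133. An 8-fold rule gave 1036, 1335 and 1180, then 442, then 72, 126 and 116, then 585, 469 and 596. HCEC-1CT had the highest count of genes set apart under each of these settings. The balance of higher and lower genes in all 3 lines, 500 and 558, was 1103 and 979 with a pseudocount of 0.1, 86 and 259 with 5, 1743 and 1325 at 2-fold and 152 and 290 at 8-fold. Between cancer lines it changed side too. HCT116 against DLD-1, 921 and 843, gave 1911 and 2074 with 0.1, 215 and 282 with 5 and 3054 and 3364 at 2-fold. HCT116 against SW620, 632 and 700, gave 1546 and 1393 with 0.1 and 2650 and 2270 at 2-fold. DLD-1 against SW620, 792 and 879, gave 2017 and 1715 with 0.1 and 3465 and 2668 at 2-fold.

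Scaling each library to the TPM scale, with equal totals, which raises values against the pseudocount, gave 711 genes that set DLD-1 apart, 2883 between HCT116 and DLD-1 and 2689 between DLD-1 and SW620. Scaling also moved the split of higher and lower genes by more than 10 percentage points: in HCT116 from 1684 and 933 to 1355 and 1187 with the median ratio and 1873 and 1679 on the TPM scale, in DLD-1 from 1722 and 1039 to 1407 and 1284 with the median ratio. On the TPM scale, HCT116 was set apart by 298 and 94 genes, against 236 and 36, and stood 1075 above and 1808 below DLD-1, while DLD-1 stood 1541 above and 1148 below SW620. Median-ratio scaling gave 420 higher and 686 lower genes in all 3 lines. With the added coding-total scaling DLD-1 against SW620 gave 840 and 833. For main transcripts, a loss of 30 percentage points gave 256 genes in all 3 lines and 860, 825 and 846 in HCT116, DLD-1 and SW620. A loss of 70 points gave 26 and 111, 116 and 106; a minimum of 1 FPKM gave 186 and 644, 615 and 625; a minimum of 20 FPKM gave 25 and 111, 99 and 111. Protein-coding transcripts alone gave 110 genes in all 3. Other causes were not tested.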

Other observations

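HOX genes, which carry positional identity along the body axis, were higher in the cancer lines as a list, with medians of 0.97, 1.51 and 1.31 in HCT116, DLD-1 and SW620 and 5 of 28 measured members 2-fold or more higher in all 3. HOXB8 stood at 0.0517, 8.25, 38.2 and 21.3 FPKM in HCEC-1CT, HCT116, DLD-1 and SW620, HOXB9 was listed at 0, 6.23, 107 and 16.5 FPKM, and HOXA9 stood at 6.65, 54.4, 36.1 and 33.5 FPKM. HOXB2 went the other way, at 14.4, 0.553, 1.11 and 0.956 FPKM. This list was no longer called without a filter on low values or among members at 5 FPKM or more. Among long noncoding RNAs, MEG3, an imprinted RNA, was listed at 70.3, 0, 0 and 0.00400 FPKM, CRNDE at 0, 3.35, 12.2 and 8.70 FPKM, and LINC00511 stood at 0.251, 15.5, 35.9 and 64.6 FPKM.

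Metabolic lists that were not called in all 3 lines still held large single differences. Glycolysis genes had medians of 0.05, 0.90 and 1.01, above random lists in DLD-1 and just within the range in SW620, at the 97.3 percentile. Oxidative phosphorylation genes had 0.89, 0.76 and 1.02, above in SW620. They were just within the range in HCT116 and DLD-1, at the 97.1 and 97.3 percentiles. The glucose transporter SLC2A1 stood at 40.0, 179, 489 and 1129 FPKM, and BNIP3, a mitophagy receptor induced by hypoxia, at 75.8, 17.1, 0.0512 and 0.135 FPKM. ALDOC, an aldolase, stood at 11.8, 117, 60.7 and 86.6 FPKM, and the lipid droplet protein PLIN2 at 333, 10.5, 0.665 and 119.8 FPKM. DPYD, which breaks down fluorouracil, was listed at 9.59, 0.410, 0.00457 and 0 FPKM. Among apoptosis genes, whose list medians ran from -0.20 in DLD-1, below random lists, to 0.03 in SW620, BIK stood at 0.231, 15.9, 30.3 and 39.1 FPKM and BCL2A1 was listed at 81.5, 0.0383, 0 and 0 FPKM. UCHL1, fixed as a neuronal marker, was listed at 35.3, 0, 0.0543 and 0 FPKM. In the order HCT116, DLD-1 and SW620, the other lists not called had medians of 0.41, 0.16 and 0.41 for oxidative stress genes, 0.29, 0.85 and 0.17 for driver genes, which were above random lists in DLD-1, 0.16, -0.02 and 0.27 for neuronal markers, 0.40, 0.26 and 0.19 for immediate early and heat shock genes and -0.13, 0.38 and 0.50 for housekeeping genes, a control that lay below random lists in HCT116, at the 1.555 percentile. Of the endothelial markers, of which only 5 of 11 were measured, ENG stood at 18.4, 1.23, 0.370 and 1.71 FPKM.

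The comparison in this paragraph was chosen only after the results were seen. Chromosome 18 genes were low in SW620: over 170 protein-coding genes with a mean of at least 1 FPKM, their median lay 0.72 below that of all 12197 autosomal genes against HCEC-1CT, 0.52 below against HCT116 and 0.84 below against DLD-1, the lowest of the 22 autosomes each time. The 2.5 percentile of random sets of 170 genes lay at -0.20, -0.14 and -0.18. Such shifts were common, with 9, 9 and 14 of the 22 autosomes outside their random ranges, and all 3 comparisons share the SW620 library. The same shift, put as a share of genes, was not confined to a few genes such as SMAD4. At least 70.6% of the chromosome 18 genes lay below the median of all genes against each line. This share restates the low medians and is not a separate test of a cause. Fewer copies of chromosome 18 was not tested and remains open, since DNA copy number was not analysed here. Chromosome 20 genes were highest of the 22 in SW620 against all 3 other lines, by 0.38, 0.39 and 0.55.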
